A study of Arabidopsis thaliana with 12 samples.

How the data were processed

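Leaves of Arabidopsis thaliana plants of 4 genotypes were profiled on 12 Affymetrix arrays. The sample characteristics give an age of 4 weeks and the growth protocol 3 to 4 weeks. The labels give a growth chamber with a fixed temperature, humidity and day length, Trizol extraction and the manufacturer's biotin labelling. Genotypes were taken from the sample characteristics and replicate numbers from the sample titles, which call the replicates biological. They do not say whether the plants were grown apart, so p-values measure the spread between these samples. The labels name no scan date, chip batch or day of harvest, so no batch could be tested.

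The values are signal intensities on a linear scale, as deposited by the authors in the series table. Each array had a trimmed mean of 499.8 or close to it, as after scaling to a common target. The submitters' processing notes name Affymetrix Expression Console 1.0, and the summary algorithm and the scaling are not given in the sources used here. The deposited scaling was kept. The table held 22810 probe sets, and 64 control probe sets were left out of the comparisons, which leaves 22746. Values of control probe sets come from a separate fit of all 22810, over which their p-values were adjusted. Probe sets were named through the platform annotation, with symbols updated by gene number from a RefSeq table of assembly TAIR10.1, from which only names and the order of genes were used. A single gene was given for 13513 probe sets, several for 503 and none for 8794. Of the single-gene probe sets 13436 matched the table and 77 did not, and they covered 13286 genes, of which 13142 had 1 probe set, 139 had 2 and 5 had more. Only probe sets with a single gene were named in the text, and a gene with several was represented by the probe set with the highest mean.

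Values were transformed to log2(signal + 16). Differences are on that scale and understate the change of dim genes. All 12 arrays were fitted together in limma 3.58.1 under R 4.3.3 with a mean for each genotype, so that the genotypes share 1 estimate of the spread. Contrasts were moderated with eBayes and tested on both sides, p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and an adjusted p under 0.05 was called. All adjusted p-values of genes come from this fit. The 6 pairwise comparisons of genotypes and a moderated F test over the contrasts against wild type were made. A probe set changed in ssi2 was counted as reversed by a second mutation where it passed the threshold between the corresponding genotype and ssi2 with the opposite sign. That count was also simulated over 20 draws of all 12 arrays, with independent noise for each probe set and no effect of a second mutation. The ssi2 arrays of a draw were in both comparisons.

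Before the data were examined, the design, the alternatives, 25 gene lists and the rule for named genes were fixed. The lists covered defence, hormone, lipid, photosynthesis and stress genes and markers of other organs and cell types. Of their 366 members 38 were measured by a single-gene probe set, in 17 lists. For this reason 29 further groups with 512 measured members were drawn from the annotation before any genotypes were compared. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of its kind within a comparison. Over the 6 comparisons camera called 19 results of the fixed lists and 45 of the added groups. With the correlation estimated per list, 1 of the 19 and 0 of the 45 passed the threshold. The rule named the 8 highest and 8 lowest genes past the threshold, with no overlap between the arrays of the genotypes, in the comparisons of ssi2 with wild type and of each second mutation with ssi2, and 4 of each in the other comparisons. Of each list it took up to 4 called members, or the largest difference where no member was called. Genes the rule named whose call was lost without some array are named in the text only with that loss.

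Replicates were compared before averaging. Within a genotype the median absolute log2 difference between arrays was 0.245 to 0.565, and no pair held identical values. Arrays have no read depth, and their number limits the precision. The fit was tested on simulated data for ssi2 against wild type, with 200 of 22746 probe sets changed in each of 10 draws. It recovered 5.9% of those changed by a log2 difference of 1 and 71.7% of those changed by 2, with 3.6 false calls on average, and made 0 calls between the unchanged groups. The noise was drawn independently for each probe set, without structure shared across probe sets. These numbers are therefore not error rates for the real arrays.

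The alternatives were quantile normalization, median centring, a filter at the 40th percentile of mean signal, the replicate number as a block, fits of only the 6 arrays compared, array weights, a trended and robust variance prior, averaging per gene, pseudocounts of 1 and 64, an added demand for a log2 difference of at least 1, an estimated inter-gene correlation, and leaving out each array in turn. Leaving out both arrays that stood apart, wild type replicate 2 and ssi2 replicate 3, was added after the principal components had been seen. The variance prior used statmod 1.5.0, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.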

Results

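Transcript levels were measured in leaves of Arabidopsis thaliana plants, labelled as 4 weeks old, on 12 Affymetrix arrays, 1 array for each sample. The plants were wild type Col-0, the ssi2 mutant, and ssi2 plants that also carried the act1 or the sid2 mutation, with 3 replicates of each of the 4 genotypes. SSI2 encodes a plastid desaturase that makes oleic acid, ACT1 encodes a plastid acyltransferase that uses oleic acid, and SID2 encodes an isochorismate synthase of salicylic acid synthesis. The series title places the comparison of these genotypes in a study of oleic acid, nitric oxide and defence. The 3 mutated genes, the nitric oxide genes NOA1, NIA1 and NIA2 and the defence markers PR1, PR2 and PR5 had no probe set with a single gene name in the annotation used, so they were not analysed here. Array medians lay between signals of 95.7 and 158, and between 16.9% and 21.8% of probe sets had a signal under 16. Replicates of a genotype correlated with Pearson's r between 0.914 and 0.982 across probe sets, which are not independent replicates. The arrays of wild type replicate 2 and ssi2 replicate 3 stood apart from the others of their genotype. The first had a value of -98.8 on the principal component that carried 15.1% of the variance. The second had -92.9 on the component that carried 17.5% and a 25S rRNA control signal of 1817, against 174 to 600 on the other arrays. The number of arrays limits the precision of every value below. Where the signals of a genotype lay under 16, such as those of AT2G15130 in wild type, the size of a log2 difference depends on the pseudocount.

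The first comparison set the ssi2 line against wild type. AT2G15130 was higher in ssi2 than in wild type, with a log2 difference of 9.03 (SE 0.774, n = 3 arrays per genotype, limma adjusted p = 5.99e-05). THI2.1, which encodes an antimicrobial thionin, rose from 5.61 ± 0.361 to 11.26 ± 1.3 on the log2 scale (SD, n = 3), a difference of 5.65 (SE 0.542, adjusted p = 8.99e-05). OSM34, an osmotin of the pathogenesis-related proteins, rose by 5.59 (SE 0.896, adjusted p = 0.00218). The other genes among the 8 largest increases were AT3G48640 at 7.03, AT3G13610 at 6.25, AT1G76960 at 6.05, AOP3 at 5.76 and AT4G00700 at 5.35. The largest decreases were AT1G23130 at -8.08 (SE 0.383, adjusted p = 1.07e-06) and ECS1, which went from 14.09 ± 0.334 in wild type to 6.95 ± 0.101 in ssi2 (SD, n = 3), a difference of -7.14 (SE 0.243, adjusted p = 4.48e-08). The others were AT3G43740 at -5.88, ZW9 at -5.04, AT2G01090 at -5.02, AT4G20480 at -4.93, AT3G22240 at -4.85 and AT1G62510 at -4.65. Of these 8 genes, 6 (all but AT3G43740 and AT3G22240) belonged to 61 genes that were lower in ssi2 and higher again in both ssi2 act1 and ssi2 sid2. Of those 61 genes, 60.7% had another of them 5 to 50 measured genes away on the same chromosome, against a median of 34.4% in random sets of the same size. The sample titles name Col-0 only for wild type. For those 61 genes an effect of the ssi2 mutation was not separated from a difference between the lines in linked segments. For the other genes a difference between the lines apart from the named mutations was not tested either. This also holds for genes lower in all 3 mutant lines, such as AT3G43740. Of 53 such genes, 22.6% had another of them 1 to 4 measured genes away, against a median of 3.77% in random sets.

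Salicylic acid response genes rose in ssi2. Of the 3 measured members of the list fixed in advance, 2 rose, and 2 when adjusted over the list alone (camera adjusted p = 0.00205, but adjusted p = 0.078 with an estimated correlation). These were WRKY53, a transcription factor of leaf senescence and defence, at 3.38 (SE 0.34, adjusted p = 0.000123), and GRX480, a glutaredoxin induced by salicylic acid, at 2.76 (SE 0.41, adjusted p = 0.0014). Both measured pattern receptor genes rose, EFR, the receptor for bacterial elongation factor Tu, by 2.79 (SE 0.337) and the kinase gene BIK1 by 1.32 (SE 0.233). The count adjusted over the list alone was also 2 (camera adjusted p = 0.00296, and adjusted p = 0.0826 with an estimated correlation). Among 21 named defence genes, a group drawn from the annotation after the values had been opened and before any genotypes were compared, 14 rose and 1 fell (camera adjusted p = 4.68e-10, and adjusted p = 0.105 with an estimated correlation). They included SAL2 at 4.56 and WRKY6 at 4.13, and the gene that fell was CSA1, an immune receptor of the nucleotide-binding class, with -2.54 (SE 0.306, adjusted p = 0.000366). The signals of CSA1 in ssi2 lay near the floor of the log2 scale. Of 13 further loci, grouped here as salicylic acid marker loci and drawn in the same way, 12 rose, among them the chitinase gene CHI at 4.97, AT5G55450 at 5.08 and AT1G13470 at 4.81 (camera adjusted p = 7.42e-12, and adjusted p = 0.105 with an estimated correlation). Whether each of these loci responds to salicylic acid was not tested.

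Of the 3 measured members of the cold and abscisic acid list fixed in advance, 2 fell in ssi2 over all probe sets and 3 when adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.078 with an estimated correlation). COR15A, which encodes a chloroplast protein that protects membranes during freezing, fell by 2.83 (SE 0.41, adjusted p = 0.0012), and COR15B fell by 2.18 (SE 0.328, adjusted p = 0.00151). The wider group of 13 cold and drought genes, which holds these 3 and was drawn from the annotation, moved both ways, with 4 lower and 1 higher (camera adjusted p = 0.0399, and adjusted p = 0.566 with an estimated correlation). Without both arrays that stood apart 3 were lower and 3 higher. The other lower genes were XERICO, chosen after its values had been seen, at -2.09 (SE 0.348, adjusted p = 0.00273) and AtLEA4-1 at -2.81 (adjusted p = 0.0251). The call of AtLEA4-1 was lost without ssi2 replicate 1 or 3 (0.0572 and 0.0771), with only the 6 arrays compared (0.105), at a pseudocount of 64 (0.0657) and without both arrays that stood apart (0.0703), from a range of 0.012 to 0.105. The gene that rose was STZ, which encodes a zinc finger protein, at 3.34 (SE 0.611, adjusted p = 0.00468), and COR27 had -1.19 (adjusted p = 0.401). The list of other acyl desaturases moved both ways, with AT5G16240 at -1.97 (SE 0.35, adjusted p = 0.00394), AT3G02630 at -1.22 and AT5G16230 at 0.98. All 3 passed the threshold, over all probe sets and when adjusted over the list alone, and the list as a whole did not (camera adjusted p = 0.284). AT5G16240 kept its call without any single array. The call of AT3G02630 was lost without wild type replicate 1 or 3, ssi2 replicate 1 or 2 or ssi2 sid2 replicate 1 (adjusted p of 0.0707, 0.126, 0.0985, 0.092 and 0.051), with only the 6 arrays compared (0.0714) and at a pseudocount of 1 (0.0651), from a range of 0.00175 to 0.126 over all alternatives. That of AT5G16230 was lost without wild type replicate 1 or 3 or ssi2 replicate 2 (0.0578, 0.1 and 0.124), after quantile normalization (0.0955) and median centring (0.173), with the replicate block (0.0552), with only the 6 arrays compared (0.122), at a pseudocount of 1 (0.0525) and without both arrays that stood apart (0.0599), from a range of 0.000342 to 0.173. The 3 measured genes of fatty acid synthesis held no call, over all probe sets or when adjusted over the list alone. Of 47 UDP-glycosyltransferase genes, 7 rose and 0 fell, with UGT73D1 at 4.57, UGT71B6 at 3.83 and UGT87A2 at 3.54, and the group's camera adjusted p was 0.0503. Without ssi2 replicate 3 the number that rose was 12. IAA29, an auxin response repressor, fell by 4.3 (SE 0.42, adjusted p = 0.000103). Among markers of other leaf or root cells, the root gene PYK10, the 1 called member of 3, had a difference of 1.84 (adjusted p = 0.0448). Its call was lost without any single array but ssi2 replicate 3 (adjusted p from 0.0568 without ssi2 act1 replicate 1 to 0.171 without ssi2 replicate 2), after quantile normalization (0.0503) and median centring (0.0853), with only the 6 arrays compared (0.168) and at pseudocounts of 1 and 64 (0.0589 and 0.0679), from a range of 0.00017 to 0.171 over all alternatives. The stomatal gene FMA had 0.29 (adjusted p = 0.6), which turned to -0.007 after quantile normalization and -0.013 after median centring.

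In all, 1312 probe sets were higher and 987 lower in ssi2 than in wild type, of which 1255 and 882 differed by at least 1 on the log2 scale. They covered 657 genes that were higher and 559 that were lower. In 2264 of the 2299 probe sets the arrays of the genotypes did not overlap, as in 25.2% of all probe sets tested, where chance gives 10%. The counts moved by more than 1.5 times without wild type replicate 1 (869 and 630), wild type replicate 3 (651 lower) and ssi2 replicate 2 (714 and 577), with only the 6 arrays compared (697 and 464), after median centring (1719 lower) and with array weights (4410 and 3310). The share of calls that were higher was 57.1%, against 44.4% after quantile normalization and 34.1% after median centring, which shifted the median difference of all probe sets from 0.08 to -0.22.

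**Figure D1:**
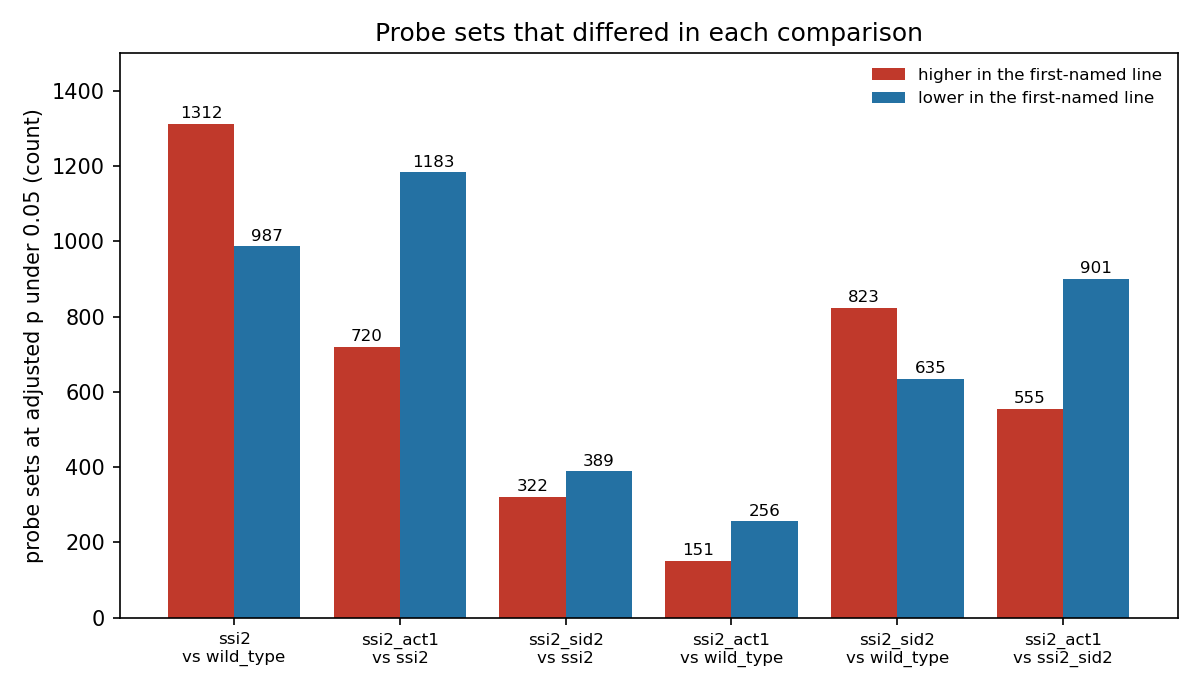
Bars give the number of probe sets higher and lower at a limma adjusted p under 0.05 in each of the 6 comparisons, with 3 arrays per genotype. The ssi2 mutant against wild type had the most calls, 1312 higher and 987 lower, and ssi2 act1 against wild type the fewest, 151 and 256.

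The second comparison asked what the act1 mutation changed in the ssi2 background. The genes that ssi2 had raised were among the largest decreases. OSM34 fell by 5.86 (SE 0.896, adjusted p = 0.0023), THI2.1 fell by 5.54 (SE 0.542, adjusted p = 0.000183) to 5.71 ± 0.215 (SD, n = 3), and AT3G13610, AT1G76960 and AT1G57650 had differences of -5.73, -5.43 and -5.33. CHI fell by 6.45 (SE 1.032, adjusted p = 0.00288). The largest increases were ECS1 at 7.61 (SE 0.243, adjusted p = 2.13e-08), AT1G23130 at 7.24, AT1G62510 at 5.62, AT3G22240 at 5.56, AT2G01090 at 5.10, AGL87 at 4.78, ZW9 at 4.71 and AT4G20480 at 4.41. All of these but AT3G22240 belonged to the 61 genes whose positions are described above.

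Salicylic acid response genes fell with act1. WRKY53 fell by 3.38 (SE 0.34, adjusted p = 0.000202) and GRX480 fell by 2.41 (SE 0.41, adjusted p = 0.004), so that 2 of 3 measured members were lower, also when adjusted over the list alone (camera adjusted p = 0.00346, and adjusted p = 0.172 with an estimated correlation). Of the 21 named defence genes 14 fell and 0 rose, among them SAL2 at -4.49 and the ubiquitin ligase gene PUB23 at -3.23 (camera adjusted p = 3.65e-10, and adjusted p = 0.152 with an estimated correlation), and 9 fell without ssi2 replicate 2, while 2 rose after median centring and 1 without ssi2 sid2 replicate 2. Of the 13 salicylic acid marker loci 8 fell, with AT1G13470 at -4.25 and AT3G60420 at -4.12 (camera adjusted p = 8.54e-09, and adjusted p = 0.152 with an estimated correlation). CSA1 did not follow these genes, with a difference of -0.16 (SE 0.306, adjusted p = 0.826), which turned to 0.126 after median centring. In the cold and abscisic acid list COR15A had a difference of 1.83 (adjusted p = 0.018), and 1 of 3 members rose over all probe sets and 3 when adjusted over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.179 with an estimated correlation). The call of COR15A was lost without ssi2 replicate 2, ssi2 act1 replicate 1 or ssi2 act1 replicate 2 (adjusted p of 0.0684, 0.058 and 0.0718) and with only the 6 arrays compared (0.0512), from a range of 0.00556 to 0.0718 over all alternatives. It was the 1 higher gene of the 13 cold and drought genes, with 1 lower (camera adjusted p = 0.53), and 3 were higher after median centring and without ssi2 replicate 3 or ssi2 sid2 replicate 2. Without both arrays that stood apart 3 were higher and 4 lower. The lower gene was STZ at -2.56 (adjusted p = 0.0239), whose call was lost without ssi2 replicate 1 or 2 (0.0896 and 0.0984) or any 1 of the ssi2 act1 arrays (0.0536, 0.0804 and 0.067), from a range of 0.000191 to 0.0984. Of the 47 UDP-glycosyltransferase genes 9 fell and 2 rose, with UGT73D1 at -4.59 and UGT87A2 at -3.73. The group's camera adjusted p was 0.0182, and its camera p was 0.0738 with an estimated correlation, which was not called once adjusted. Without ssi2 replicate 3 the number that fell was 14.

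Between ssi2 act1 and ssi2, 720 probe sets were higher and 1183 lower (636 and 1143 with a log2 difference of at least 1), for 442 and 545 genes. The genotypes did not overlap in 1894 of these 1903 probe sets and in 24% of all probe sets tested, where chance gives 10%. These counts moved by more than 1.5 times without ssi2 replicate 1 (434 higher), ssi2 replicate 2 (298 and 589), ssi2 act1 replicate 2 (400 and 737) and ssi2 act1 replicate 3 (338 and 724), and rose to 1181 and 1936 without both arrays that stood apart. They also moved so with only the 6 arrays compared (441 higher), at a pseudocount of 1 (424 higher), after median centring (1382 higher) and with array weights (2845 and 4397). The share of calls that were higher was 37.8%, against 51.0% after quantile normalization and 62.9% after median centring.

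The third comparison asked what the sid2 mutation changed in the ssi2 background. OSM34 fell by 6.62 (SE 0.896, adjusted p = 0.00249) to 4.80 ± 0.367 (SD, n = 3), THI2.1 fell by 5.18 (SE 0.542, adjusted p = 0.000487), and GH3.3, which encodes an enzyme that joins auxin to amino acids, fell by 6.03 (SE 0.657, adjusted p = 0.000666). Differences for AT1G57650, UGT73D1 and AT1G30700 were -5.01, -4.18 and -4.02. The largest increases were AT1G23130 at 7.53, ECS1 at 7.41 (SE 0.243, adjusted p = 2.93e-08), AGL87 at 5.42, AT1G72920 at 5.29, AT2G01090 at 4.97, AT4G19500 at 4.72, AT4G20480 at 4.57 and AT4G16880 at 4.36. All of these but AT1G72920 belonged to the 61 genes described above.

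The salicylic acid response list held 1 lower member of 3, GRX480 at -2.03 (SE 0.41, adjusted p = 0.0214), and 2 when adjusted over the list alone, and it did not pass the test as a whole (camera adjusted p = 0.246). The call of GRX480 was lost without ssi2 replicate 1, ssi2 replicate 2, ssi2 sid2 replicate 1 or ssi2 sid2 replicate 3, with an adjusted p of 0.0677, 0.0837, 0.0782 and 0.113 in that order, after quantile normalization and median centring (0.0502 in both) and at a pseudocount of 1 (0.0614), from a range of 4.68e-05 to 0.113 over all alternatives. Of the 13 salicylic acid marker loci 3 fell and 1 rose (camera adjusted p = 0.00113, and adjusted p = 0.446 with an estimated correlation). AT4G23610 fell by 2.19 (SE 0.362, adjusted p = 0.00799), and its call held under every alternative. AT1G13470 had -1.89 and AT1G02360 had -1.62 (adjusted p = 0.0471 and 0.0458), and each lost its call in 13 alternatives, with an adjusted p of up to 0.168 and 0.192 from lows of 0.00056 and 0.000456. The higher locus was AT1G35710 at 1.31 (adjusted p = 0.0395), whose call was lost in 12 alternatives, 9 of them without a single array (from 0.00022 to 0.178). The number that fell was 1 after quantile normalization and without wild type replicate 1, ssi2 replicate 2 or 3, ssi2 act1 replicate 2 or ssi2 sid2 replicate 1 or 3, and 5 without wild type replicate 2. Of the 21 named defence genes 5 fell and 0 rose, among them the chitinase gene ChiC at -2.63 (SE 0.344, adjusted p = 0.00193) and UGT76B1 at -2.77 (SE 0.477, adjusted p = 0.00988). The group's camera adjusted p was 1.94e-06, and its adjusted p was 0.446 with an estimated correlation. The number that fell was 3 without ssi2 replicate 2, ssi2 sid2 replicate 1 or ssi2 sid2 replicate 3 and after median centring, and 9 without wild type replicate 2. In the counts after median centring and quantile normalization and without wild type replicate 2 or ssi2 replicate 2, 1 gene of the group rose. The plastid-encoded ribosomal protein genes rpl33 and rps16 rose by 2.77 (SE 0.367, adjusted p = 0.00218) and 2.48 (SE 0.352, adjusted p = 0.0035), 2 of 19 members of that group. Its camera adjusted p was 9.57e-05, and its camera p was 0.105 with an estimated correlation, which was not called once adjusted. EFR had a difference of -0.76 (adjusted p = 0.288).

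Between ssi2 sid2 and ssi2, 322 probe sets were higher and 389 lower (318 and 383 with a log2 difference of at least 1), for 196 and 205 genes. The arrays of the genotypes were apart in all of these 711 probe sets and in 23.9% of all tested, where chance gives 10%. The counts moved by more than 1.5 times without wild type replicate 2 (505 and 621), ssi2 replicate 2 (162 lower), ssi2 replicate 3 (172 and 257), ssi2 sid2 replicate 1 (114 and 162), ssi2 sid2 replicate 2 (242 lower) and ssi2 sid2 replicate 3 (109 and 124), at a pseudocount of 1 (175 and 204) and with array weights (2087 and 3417). The share of calls that were higher was 45.3%, against 61.4% after median centring, 55.0% after quantile normalization, 52.6% with the filter on mean signal and 58.9% without ssi2 replicate 2.

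How far the double mutants lay back towards wild type was counted over the 2299 probe sets changed in ssi2. WRKY53 stood at 6.89 ± 0.41 in wild type, 10.28 ± 0.198 in ssi2, 6.90 ± 0.268 in ssi2 act1 and 9.01 ± 0.673 in ssi2 sid2 (SD, n = 3). COR15A stood at 12.61 ± 0.445, 9.78 ± 0.373, 11.60 ± 0.823 and 9.0 ± 0.427 in the same order. THI2.1, OSM34, ECS1 and AT1G23130 lay back towards wild type in both. In ssi2 act1, 1159 of the 2299 probe sets (50.4%) passed the threshold in the opposite direction, 756 that ssi2 had raised and 403 that it had lowered. In ssi2 sid2 these were 471 (20.5%), 308 and 163. Still past the threshold against wild type in the direction of ssi2 were 229 in ssi2 act1 and 803 in ssi2 sid2. Reversed in both were 252 raised and 108 lowered probe sets. The 61 genes that lay near each other, ECS1 and AT1G23130 among them, come from these 108. For them an effect of the second mutations was not separated from a difference between the lines in linked segments.

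The reversal counts share the ssi2 arrays with the ssi2 comparison. In simulated arrays of the same design, with the ssi2 arrays of each draw in both comparisons, unchanged groups gave 0 reversed probe sets. With the ssi2 effect and no effect of a second mutation they gave 0.1 on average for act1 and 0 for sid2, over 20 draws. The draws with the ssi2 effect called 4484 probe sets changed in ssi2 on average, against 2299 in the data. Their noise was drawn independently for each probe set, without the structure across probe sets that set some real arrays apart. The counts near 0 are therefore not a chance level for these arrays. The part of the shared arrays where both effects are real was not simulated. Independent lists of these sizes would overlap in 68.2 raised and 31.2 lowered probe sets for act1 and 22.4 and 14.0 for sid2. Independent lists of the calls against wild type, which share the wild type arrays, would overlap in 8.71 raised and 11.1 lowered probe sets for act1, where 78 and 151 were observed, and in 47.5 and 27.6 for sid2, where 391 and 412 were. The wild type arrays were not split between these comparisons, and part of the excess in these calls may come from them. The reversal counts moved by more than 1.5 times without ssi2 replicate 2 (587 for act1, 223 for sid2), ssi2 sid2 replicate 1 (227 for sid2), ssi2 sid2 replicate 3 (198 for sid2) and both arrays that stood apart (1851 for act1), at a pseudocount of 1 (259 for sid2) and with array weights (4336 and 3019).

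**Figure D2:**
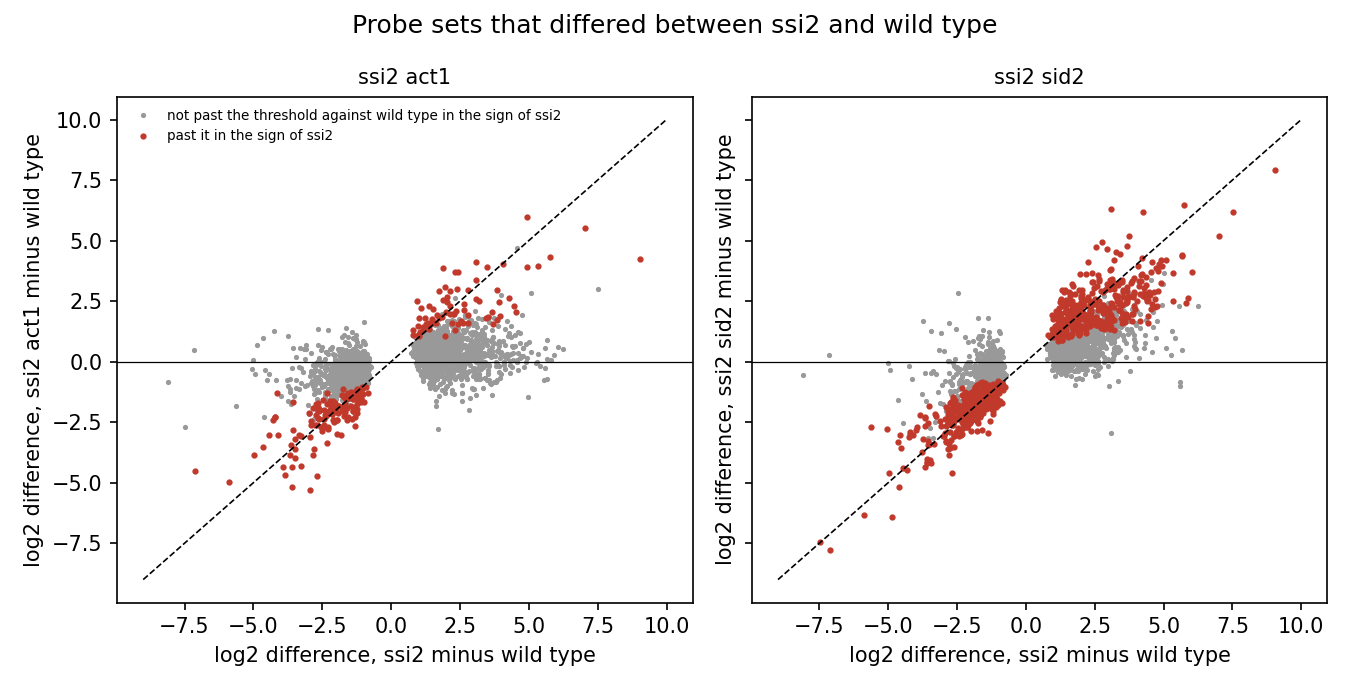
Each point is 1 of the 2299 probe sets changed in ssi2, with the log2 difference of ssi2 minus wild type on the horizontal axis and that of ssi2 act1 (left) or ssi2 sid2 (right) minus wild type on the vertical axis, each from 3 arrays per genotype. The dashed line marks equal differences, and the 229 and 803 probe sets in red passed the threshold against wild type in the direction of ssi2.

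The fourth comparison set ssi2 act1 against wild type. AT3G48640 was higher by 5.50 (SE 0.593, adjusted p = 0.00253). PDF1.2b, which encodes a plant defensin, fell by 5.31 (SE 0.822, adjusted p = 0.00864), from 10.74 ± 1.66 to 5.43 ± 0.325 (SD, n = 3). It was also lower in ssi2 alone than in wild type, by a difference of -2.96. That difference was not called with only the 6 arrays compared (limma adjusted p = 0.101). AT3G43740 fell by 4.97 (SE 0.615, adjusted p = 0.00325), and AT5G44520 and AT5G45500 had -4.66 and -4.34. CSA1, the 1 measured resistance gene, fell by 2.70 (SE 0.306, adjusted p = 0.00264), also when adjusted over its list of 1, which adds nothing. It was lower in all 3 mutant lines, with signals near the floor of the log2 scale. An effect of the mutations on CSA1 was not separated from a difference between the lines. Of the 21 named defence genes only EFR, at 1.59, rose and only CSA1 fell (camera adjusted p = 0.452). The call of EFR was lost without wild type replicate 1 or 3 (adjusted p of 0.117 and 0.137), any 1 of the ssi2 act1 arrays (0.104, 0.0872 and 0.13) or ssi2 sid2 replicate 1 or 3 (0.0638 and 0.0567), after median centring (0.0502), with the replicate block (0.0622), with only the 6 arrays compared (0.0687) and at a pseudocount of 64 (0.174), from a range of 0.00706 to 0.174 over all alternatives. Of the 13 salicylic acid marker loci 1 was higher (camera adjusted p = 0.0877), AT4G23610 at 1.73 (adjusted p = 0.0356), whose call was lost in 13 alternatives, 7 of them without a single array (from 0.00149 to 0.143). In this group 2 were higher without ssi2 replicate 1, ssi2 replicate 3 or both arrays that stood apart. GRX480 had a difference of 0.35 (adjusted p = 0.842) and WRKY6 of 1.33 (adjusted p = 0.222). The jasmonate and ethylene defence list held 1 lower member of 3 over all probe sets and 2 when adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.262 with an estimated correlation).

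Between ssi2 act1 and wild type, 151 probe sets were higher and 256 lower, all by at least 1 on the log2 scale, for 80 and 133 genes. The arrays of the genotypes were apart in all of these 407 probe sets and in 16.5% of all tested, where chance gives 10%. The counts moved by more than 1.5 times without wild type replicate 1 (65 and 123), wild type replicate 3 (75 and 141), ssi2 act1 replicate 1 (95 and 167), ssi2 act1 replicate 2 (79 and 147) and ssi2 act1 replicate 3 (68 and 127), and rose to 294 and 505 without both arrays that stood apart. They were 30 and 62 with only the 6 arrays compared and 815 and 1044 with array weights, and 163 were lower at a pseudocount of 1. With ssi2 act1 replicate 1 and wild type replicate 2 exchanged, 401 probe sets were called, against 407 with the genotypes as labelled.

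The fifth comparison set ssi2 sid2 against wild type. AT2G15130 was higher by 7.91 (SE 0.774, adjusted p = 0.000483), AOP3 by 6.47, AT5G04380 by 6.32 (SE 0.748, adjusted p = 0.00102) and AT5G55570 by 6.17. AT3G22240 fell by 6.42 (SE 0.453, adjusted p = 1e-04), and AT3G43740, IAA29 and AT3G44430 had differences of -6.32, -4.47 and -4.40. All 3 measured members of the cold and abscisic acid list fell, over all probe sets and when adjusted over the list alone, COR15A with -3.6 (SE 0.41, adjusted p = 0.00095), COR15B with -2.27 and COR47 with -2.96 (camera adjusted p = 1.64e-05). This list also passed with an estimated correlation (adjusted p = 0.043). COR47 had an adjusted p of 0.0528 without ssi2 sid2 replicate 3, the highest of its alternatives, whose lowest was 0.00024. Of the wider group of 13 cold and drought genes 6 fell and 1 rose (camera adjusted p = 0.000149, and adjusted p = 0.434 with an estimated correlation). Of these genes 3 fell without ssi2 sid2 replicate 1 and 2 without ssi2 sid2 replicate 3. The gene that rose was STZ (adjusted p = 0.0109), whose call was lost with only the 6 arrays compared (0.0506, the highest of a range from 0.000105).

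WRKY53 was higher in ssi2 sid2 than in wild type by 2.11 (SE 0.34, adjusted p = 0.00478), the 1 salicylic acid response gene of 3 past the threshold, with 2 when adjusted over the list alone (camera adjusted p = 0.0106, and adjusted p = 0.145 with an estimated correlation). Of the 21 named defence genes 8 rose and 1 fell, with SAL2 at 3.72 and WRKY6 at 2.80 (camera adjusted p = 0.000429, and adjusted p = 0.434 with an estimated correlation). The number that rose was 5 without wild type replicate 3, ssi2 act1 replicate 3 or any 1 of the ssi2 sid2 arrays, and 2 fell without ssi2 sid2 replicate 1. Of the 13 salicylic acid marker loci 6 rose, among them AT5G39670 by 3.45, AT1G13470 by 2.92 and AT1G35710 by 2.59 (camera adjusted p = 4.18e-08, and adjusted p = 0.339 with an estimated correlation), and 3 rose without ssi2 sid2 replicate 1 or ssi2 sid2 replicate 3. CSA1 fell by 2.92 (SE 0.306, adjusted p = 0.000653), also when adjusted over its list of 1, to signals near the floor of the log2 scale.

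Between ssi2 sid2 and wild type, 823 probe sets were higher and 635 lower (800 and 595 with a log2 difference of at least 1), for 404 and 346 genes. The genotypes did not overlap in 1452 of these 1458 probe sets and in 26% of all tested, where chance gives 10%. Leaving out 1 array moved the counts by more than 1.5 times for wild type replicate 1 (439 and 329), wild type replicate 3 (482 and 341), ssi2 sid2 replicate 1 (340 and 276) and ssi2 sid2 replicate 3 (269 and 192), and the lower count rose to 1052 without both arrays that stood apart. It was 396 at a pseudocount of 1, and with array weights the counts were 2361 and 2307. The share of calls that were higher was 56.4%, against 43.6% after median centring, which shifted the median difference from 0.01 to -0.14.

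The last comparison set ssi2 act1 against ssi2 sid2 and so tested whether the effects of act1 and sid2 in ssi2 differed. PDF1.2b was lower in ssi2 act1, with a difference of -5.76 (SE 0.822, adjusted p = 0.00337), with 11.19 ± 1.41 in ssi2 sid2 (SD, n = 3). The ssi2 single mutant also lay below wild type, at -2.96, so a lower PDF1.2b was not particular to ssi2 act1. JMT, which encodes a jasmonic acid methyltransferase, had -3.01 (SE 0.501, adjusted p = 0.00598). Both belonged to 5 of 12 jasmonate genes that were lower in ssi2 act1, with 0 higher (camera adjusted p = 4.06e-06, and adjusted p = 0.304 with an estimated correlation), and 3 were lower without ssi2 sid2 replicate 1. WRKY53 had a difference of -2.11 (SE 0.34, adjusted p = 0.00535), SAL2 of -3.65 and PUB23 of -2.20. Of the 21 named defence genes 4 were lower and 0 higher (camera adjusted p = 0.00387, and adjusted p = 0.377 with an estimated correlation). Without both arrays that stood apart 7 were lower, and 1 was higher without ssi2 sid2 replicate 2. Of the 13 salicylic acid marker loci 5 were lower and 0 higher (camera adjusted p = 0.000463, and adjusted p = 0.377 with an estimated correlation). The number lower was 3 without ssi2 act1 replicate 2 and 1 without ssi2 sid2 replicate 1 or 3, and 1 was higher after quantile normalization, after median centring and without ssi2 replicate 3 or both arrays that stood apart. COR15A had 2.60 (SE 0.41, adjusted p = 0.00466), and 2 of 3 measured members of the cold and abscisic acid list were higher in ssi2 act1, 3 when adjusted over the list alone (camera adjusted p = 0.00248, and adjusted p = 0.17 with an estimated correlation). The other was COR47 at 2.65 (adjusted p = 0.0156), whose call was lost without ssi2 act1 replicate 3, ssi2 sid2 replicate 1 or ssi2 sid2 replicate 3 (adjusted p of 0.055, 0.0775 and 0.0861, from a range of 0.000395 to 0.0861 over all alternatives). Of the wider group of 13 cold and drought genes 3 were higher and 1 lower (camera adjusted p = 0.0224, and adjusted p = 0.477 with an estimated correlation). Without ssi2 act1 replicate 3, ssi2 sid2 replicate 1 or ssi2 sid2 replicate 3 these were 1 and 0. The third higher gene was COR27 at 3.61 (adjusted p = 0.018), whose call was lost without ssi2 act1 replicate 2 or 3 or ssi2 sid2 replicate 1 or 3 (0.066, 0.0589, 0.0819 and 0.0928, from a range of 0.000686 to 0.0928). The lower gene was STZ at -2.39 (adjusted p = 0.0402), whose call was lost in 10 alternatives, 8 of them without a single array (from 0.0022 to 0.121). The largest differences were AT3G22240 at 7.13 (SE 0.453, adjusted p = 2.47e-05), AT5G42760 at -6.10, AT5G04380 at -6.07 and AT2G15020 at -5.87.

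Between ssi2 act1 and ssi2 sid2, 555 probe sets were higher and 901 lower (496 and 877 with a log2 difference of at least 1), for 334 and 434 genes. The genotypes did not overlap in 1455 of these 1456 probe sets and in 26.7% of all tested, where chance gives 10%. The counts moved by more than 1.5 times without ssi2 act1 replicate 2 (211 and 474), ssi2 act1 replicate 3 (220 and 501), ssi2 sid2 replicate 1 (142 and 343) and ssi2 sid2 replicate 3 (103 and 313), and rose to 1110 and 1566 without both arrays that stood apart. At a pseudocount of 1, 303 were higher, and with array weights the counts were 2280 and 2386. The share of calls that were higher was 38.1%, against 50.9% after median centring. Across the 4 genotypes, 3269 probe sets (14.4% of those tested) passed limma's moderated F test, and 2165 did without ssi2 replicate 2, 2102 without ssi2 sid2 replicate 3 and 11006 with array weights.

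**Figure D3:**
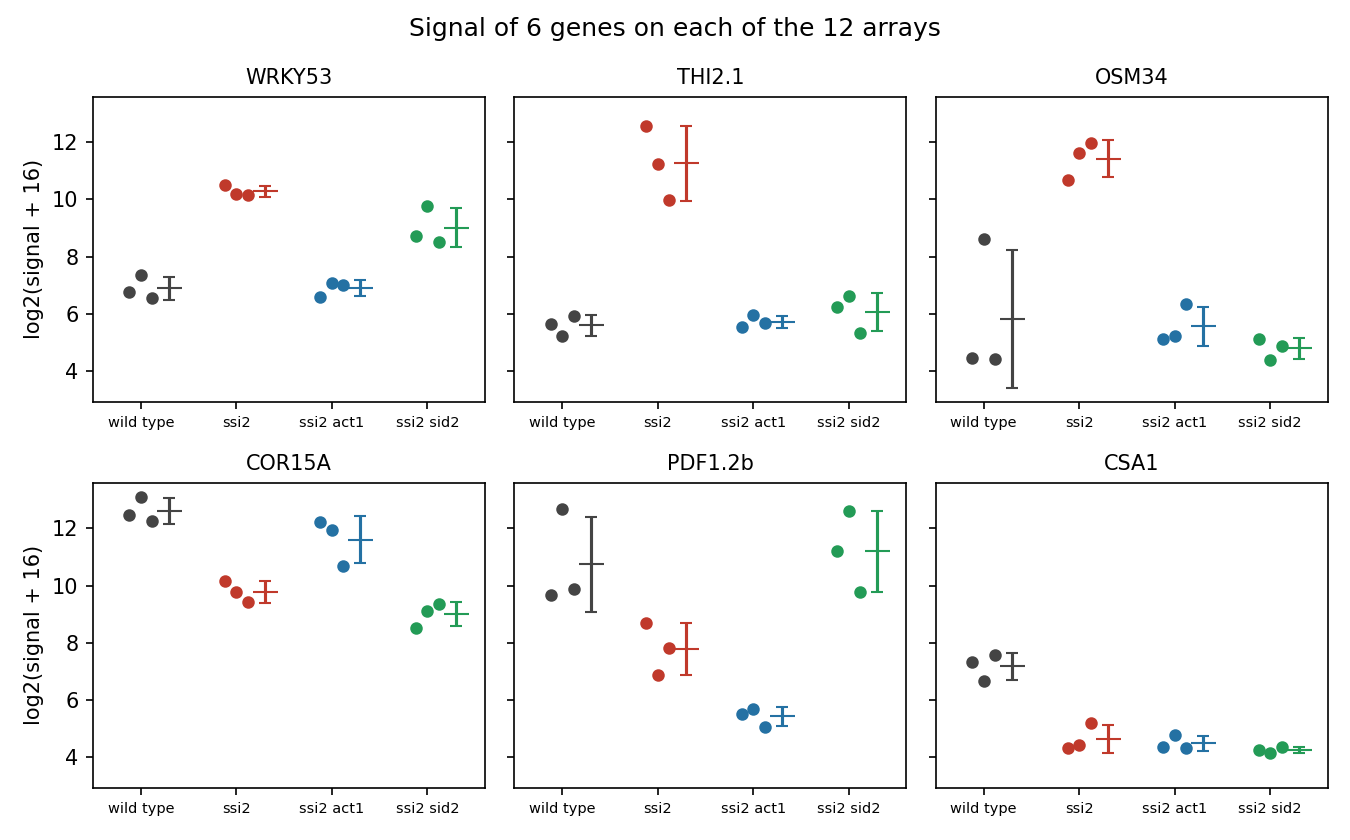
Points give log2(signal + 16) on each of the 12 arrays for WRKY53, THI2.1, OSM34, COR15A, PDF1.2b and CSA1, with bars for the mean and SD of the 3 arrays of each genotype. WRKY53 averaged 10.28 in ssi2 and 6.90 in ssi2 act1, and CSA1 averaged 7.18 in wild type and 4.65, 4.49 and 4.26 in ssi2, ssi2 act1 and ssi2 sid2.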

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

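The tests of gene position, the test of harvest time or light, the test of calls kept under other scalings and the comparison with mutant arrays held out of the fit were chosen after the results had been seen, and the other tests of this part before.

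The ubiquitin control probe set AFFX-Athal-Ubq_M_f_at, which no comparison used, had a mean signal of 3047 in wild type and 7253 in ssi2, a log2 difference of 1.37 (SE 0.359, limma adjusted p = 0.0313), while the other 4 ubiquitin probe sets had 0.14 to 0.47 (adjusted p from 0.191 to 0.758). The control probe set AFFX-r2-At-GAPDH-3_s_at had mean signals of 4507 and 9384, a difference of 1.04 (SE 0.271, limma adjusted p = 0.0298), and the other 4 GAPDH probe sets had 0.78 to 0.93 (adjusted p from 0.0642 to 0.106).

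In 10 probe sets, 4 of them with a single gene name, act1 and sid2 had called effects of opposite sign in ssi2. The difference of ssi2 act1 minus ssi2 sid2 is made up of these effects, so that its size follows from how the genes were chosen and its test adds no evidence. AT5G04380 had a difference of -6.07, with effects of -2.84 for act1 and 3.22 for sid2, and AT5G55050 had -3.05, with -1.52 and 1.53. AT3G14200 had -3.85, with -1.69 and 2.16, and AT1G55960 had -3.36, with -1.56 and 1.80. The separate effects against ssi2 are given as values only, since each lost its call without some arrays. Their adjusted p reached 0.143 for act1 (without ssi2 replicate 2) and 0.156 for sid2 (without ssi2 sid2 replicate 3) in AT5G04380, 0.106 and 0.191 without the same arrays in AT5G55050, and 0.145 and 0.0962 without them in AT3G14200. In AT1G55960 the act1 effect lost its call without ssi2 replicate 2 (0.0736) or ssi2 act1 replicate 2 (0.0585) and after median centring (0.0598), and the sid2 effect without ssi2 sid2 replicate 1 (0.0732) or replicate 3 (0.0694).

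The 61 genes that were lower in ssi2 and higher again in both double mutants lay near each other, with 31 on chromosome 1 and 19 on chromosome 4, and 60.7% had another of them 5 to 50 measured genes away, as high as in 1 of 1000 random sets. Neighbouring gene copies that share probes were argued against as the whole cause, since closer neighbours were left out and the share still exceeded 49.2%, the upper bound that the test took from random sets. They stay open for part of it, since 18.03% had another of the 61 only 1 to 4 genes away, against a median of 3.28%, and 22.6% of the 53 genes lower in all 3 mutants had another of those 53 as near, against 3.77%, where the share 5 to 50 genes away was 34.0% against 30.2%. Expression lost and regained without regard to position was argued against by a ratio of 1.76 to the median of random sets, 34.4%, while the 129 genes with the opposite course had 62.0% against a median of 58.9%. Segments of another strain's sequence in the ssi2 line may also account for part of the pattern. They could act through probes that match that sequence poorly or through its own expression, and no test here separates these. SSI2 lies on chromosome 2, which held 3 of the 61 genes. Both double mutants also carry ssi2, so a segment linked to SSI2 would tend to stay in them. Genes changed by such a segment would then not return and would not be among the 61. That number therefore does not test linkage to SSI2. An effect of the ssi2 genotype on the 61 genes without linkage stays open, untested.

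HYH, a transcription factor of light signalling, was among the genes that differed between ssi2 act1 and ssi2 sid2, and no list of light-regulated genes was tested. The authors' scaling was argued against as the whole cause, since 86.1% of the 1456 probe sets stayed called in the same direction after quantile normalization and 81.1% after median centring, where the test took 80% as its bound, and 0 turned, but it stays open for the rest, and the total of 1448 after quantile normalization does not say which genes were called. A difference in harvest time or light between samples could contribute: a score over the called genes varied within ssi2 by 0.35 of the difference between the double mutants, and within wild type by 0.0404. That range came from ssi2 replicate 3, at 0.497 of the way from ssi2 act1 to ssi2 sid2, against 0.804 and 0.847 for the other ssi2 arrays, and the score covers all called genes, so that it does not single out light. Within ssi2 sid2, whose arrays helped to choose these genes, the range was 0.288. The circadian gene GI stood at 10.3 on ssi2 replicate 3, against 7.5 and 7.4 on replicates 1 and 2. In ssi2 sid2 it stood at 9.0 on replicate 2, against 6.6 and 7.0 on replicates 1 and 3. COR27 was likewise highest on these arrays, at 11.7 and 10.9. The cause of these differences within a genotype was not tested. The difference in genotype stays open, untested.

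Wild type replicate 2 stood apart from the other wild type arrays. A mislabelled mutant array was argued against: over 55 probe sets lower in all mutants its median position between mutants (0) and wild type (1) was 0.734 (quartiles 0.262 and 0.954), where mutant arrays held out of the fit lay from -0.0733 to 0.148. The median position lay between the bounds of 0.5 and 0.8 set in advance, so that this test alone left the question open. RNA of ssi2 plants in the sample would need a share of 0.463 from 341 probe sets lower in ssi2 (quartiles -0.0941 and 0.849). From 741 higher probe sets the share was 0.114 (0.00652 and 0.383). The difference was 0.348, where at most 0.1 was set in advance. The quartiles overlap and the shares come from 1 array, so that this test does not decide the question. No biological explanation was tested, and growth or handling of this sample stays open.

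With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, had the highest count. The real count and the highest of the others were 2299 and 31 for ssi2 against wild type, 1903 and 0 for ssi2 act1 against ssi2, and 711 and 0 for ssi2 sid2 against ssi2. They were 407 and 401 for ssi2 act1 against wild type, 1458 and 2 for ssi2 sid2 against wild type, and 1456 and 0 between the double mutants. The split with 401 exchanged ssi2 act1 replicate 1 with wild type replicate 2, which points to a structure of the samples besides the genotypes. For the F test over all genotypes the real split had 3269 probe sets, the 1 highest of 100, and the highest other had 131. Chance is thus unlikely but not excluded, since 100 splits limit how small a share can be shown. The splits also treat the arrays as interchangeable.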

How the results depend on the processing

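Leaving out both arrays that stood apart was chosen after the principal components had been seen, and all other alternatives before the data were examined. Of 348 calls of named genes, from 231 (without ssi2 sid2 replicate 3) to 346 (array weights) kept their side of the threshold under an alternative in which all were measured, and 0 turned their direction. The filter measured 280 of them and kept 279. Of the 72 calls named for the size of their difference, 8 were lost under some alternative. Between 16.9% and 21.8% of probe sets had a signal under 16, where background limits what a difference can show. Of the 19 calls of fixed lists, 1 held with an estimated correlation, and of the 45 of added groups 0. Except where said, the cause of a change below was not tested.

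Counts are given as higher and lower. With array weights, from 0.249 for wild type replicate 2 to 5.78 for ssi2 replicate 2, they were 4410 and 3310 for ssi2 against wild type, 2845 and 4397 for ssi2 act1 against ssi2, and 2087 and 3417 for ssi2 sid2 against ssi2. They were 815 and 1044 for ssi2 act1 against wild type, 2361 and 2307 for ssi2 sid2 against wild type, and 2280 and 2386 between the double mutants. The F test called 11006, and 4336 and 3019 were reversed in ssi2 act1 and ssi2 sid2. Averaged per gene, which leaves fewer features, the comparisons in that order gave 642 and 550, 427 and 533, 198 and 213, 79 and 130, 390 and 337, and 308 and 416. The F test then called 1666, and 600 and 268 were reversed. In fits of only 6 arrays, which hold fewer samples, ssi2 against wild type had 697 and 464, ssi2 act1 against ssi2 had 441 higher, and ssi2 act1 against wild type had 30 and 62. Median centring gave 1719 lower in ssi2 against wild type and 1382 higher in ssi2 act1 against ssi2. A pseudocount of 1 gave 424 higher in ssi2 act1 against ssi2, 175 and 204 in ssi2 sid2 against ssi2, 163 lower in ssi2 act1 and 396 lower in ssi2 sid2 against wild type, 303 higher between the double mutants and 259 reversed in ssi2 sid2. Without both arrays that stood apart ssi2 act1 against ssi2 had 1181 and 1936, and ssi2 act1 against wild type 294 and 505. There were then 1052 lower in ssi2 sid2 against wild type, 1110 and 1566 between the double mutants and 1851 reversed in ssi2 act1. No other count moved by more than 1.5 times in these settings, and none did after quantile normalization, the filter, the trended and robust prior or a pseudocount of 64.

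Without single arrays, ssi2 against wild type had 714 to 1515 higher and 577 to 1327 lower, ssi2 act1 against ssi2 298 to 990 and 589 to 1597, and ssi2 sid2 against ssi2 109 to 505 and 124 to 621. For ssi2 act1 against wild type they were 65 to 197 and 123 to 370, for ssi2 sid2 against wild type 269 to 1013 and 192 to 832, and between the double mutants 103 to 819 and 313 to 1253. The F test called 2102 to 4234, and 587 to 1481 were reversed in ssi2 act1 and 198 to 688 in ssi2 sid2. A group left with 2 arrays shared the spread of the other genotypes.

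With the replicate number as a block, counts were 1212 and 859 for ssi2 against wild type and 567 and 1061 for ssi2 act1 against ssi2, with 315 lower in ssi2 sid2 against ssi2. The other comparisons had 117 and 190, 702 and 505, and 402 and 784 in the order above. The F test called 2723, and 1038 and 393 were reversed, so the block moved no count by more than 1.5 times. The numbers did not pair the arrays. Over 8859 probe sets, 7 of 18 same-numbered pairs had deviations that correlated over 0.1 and 6 under -0.1, from -0.562 to 0.482, and 2 of 12 arrays correlated best with their own number.

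Some differences of genes and lists that were not called turned their direction. FMA in ssi2 against wild type had -0.007 after quantile normalization and -0.013 after median centring, and BCAT4 had 0.243 with array weights and 1.06 without both arrays. CSA1 in ssi2 act1 against ssi2 had 0.126 after median centring and 0.113 without both arrays. In ssi2 sid2 against ssi2, ATHSP22.0 had -0.325 with array weights and GI 0.062 without both arrays. EXPA8 in ssi2 sid2 against wild type had -0.924 with array weights and -1.18 without both arrays, and between the double mutants 0.006 with array weights, where AT5G52810 had -0.302. Without single arrays EXPA8 ranged from -1.40 to 0.664 in ssi2 act1 and from -1.18 to 0.884 in ssi2 sid2 against wild type, and from -0.727 to 0.489 between the double mutants. GI ranged from -0.514 to 0.306 in ssi2 act1 against wild type and from -1.61 to 0.062 in ssi2 sid2 against ssi2. BCAT4 ranged from -1.31 to 0.451 in ssi2 and PDF1.2 from -0.166 to 1.95 in ssi2 sid2 against wild type. In ssi2 act1 against ssi2 FMA ranged from -0.096 to 0.346 and CSA1 from -0.324 to 0.113, and AT5G52810 ranged from -0.353 to 1.68 between the double mutants. Lists that turned had these camera adjusted p-values, all above the threshold. In ssi2 against wild type, jasmonate and ethylene defence had 0.915 after median centring and aliphatic glucosinolate genes 0.703 with array weights. Heat shock genes had 0.867 in ssi2 act1 and 0.422 in ssi2 sid2 against ssi2 with array weights, and root markers in ssi2 sid2 against ssi2 had 0.971 after median centring and 0.812 with array weights. Salicylic acid synthesis had 0.951 in ssi2 act1 against wild type with only 6 arrays and 0.964 between the double mutants after quantile normalization. In ssi2 sid2 against wild type, photosynthesis had 0.957 after quantile normalization. Fatty acid synthesis there had 0.998 after quantile normalization, 0.95 after median centring, 0.977 with the filter, 1 with the replicate block, 0.687 with array weights and 0.998 with the trended and robust prior.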

Other observations

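The genes of this part were chosen after their values had been seen, and no explanation was tested for them beyond those given above for the difference between the double mutants.

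AT5G05250 and AT1G47400, known to respond to iron shortage, were higher in ssi2 than in wild type. AT5G05250 rose by 3.68 in ssi2 act1 (SE 0.491, limma adjusted p = 0.00461) and by 2.31 in ssi2 (adjusted p = 0.0106) against wild type, and both calls held under every alternative, with adjusted p of up to 0.0299 and 0.043. In ssi2 sid2 its difference was 2.2 (adjusted p = 0.0213), and the call was lost without ssi2 sid2 replicate 2 (0.0538) and in the fit of only the 6 arrays compared (0.0929), from a range of 0.00888 to 0.0929. AT1G47400, which encodes a short peptide of the iron response, rose by 3.49 in ssi2 (adjusted p = 0.0102, up to 0.0451). Its difference in ssi2 act1 was 3.91 (adjusted p = 0.0193), with the call lost without wild type replicate 1 (0.0657), ssi2 act1 replicate 2 (0.0768) or ssi2 act1 replicate 3 (0.0989) and with only the 6 arrays compared (0.0783), from a range of 0.0017 to 0.0989. In ssi2 sid2 it was 3.29 (adjusted p = 0.0213), with the call lost without wild type replicate 1 (0.0605), ssi2 sid2 replicate 2 (0.0701) or ssi2 sid2 replicate 3 (0.0687) and with only the 6 arrays compared (0.0529), from a range of 0.00406 to 0.0701. BHLH101, a transcription factor of the iron response, had 4.52 in ssi2 act1 (adjusted p = 0.0348), with the call lost without any 1 of the wild type arrays (0.104, 0.0565 and 0.104), ssi2 replicate 2 (0.059) or any 1 of the ssi2 act1 arrays (0.0705, 0.105 and 0.135) and at pseudocounts of 1 and 64 (0.0547 and 0.0545), from a range of 0.000471 to 0.135. It had 2.67 in ssi2 (adjusted p = 0.102) and 1.23 in ssi2 sid2 (adjusted p = 0.547), where replicate 2 stood at 10.70 and the others at 6.18 and 6.23. AT1G12030, also examined as an iron gene, had 1.85 in ssi2, 2.65 in ssi2 act1 and 0.66 in ssi2 sid2 (adjusted p = 0.17, 0.134 and 0.733). PYE, a regulator of the iron response, had 0.66, 0.71 and 1.16 in the same order (adjusted p = 0.258, 0.406 and 0.0631). Neither AT5G05250 nor AT1G47400 passed the threshold between the double mutants, at adjusted p of 0.101 and 0.742.

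Hsp70-2 and MSRB9 were above wild type in ssi2 and ssi2 sid2 and did not pass the threshold in ssi2 act1. Hsp70-2, a heat shock protein gene, rose by 4.93 in ssi2 (SE 0.56, limma adjusted p = 0.00025) and by 3.96 in ssi2 sid2 (adjusted p = 0.00269) against wild type, and had 0.15 in ssi2 act1 (adjusted p = 0.965). Its difference between ssi2 act1 and ssi2 sid2 was -3.81 (adjusted p = 0.00367). MSRB9, which encodes a methionine sulfoxide reductase, rose by 4.88 and 3.94 in the same comparisons (adjusted p = 0.00033 and 0.00315) and had 0.73 in ssi2 act1 (adjusted p = 0.71). These calls of both genes held under every alternative. The difference of MSRB9 between the double mutants was -3.21 (adjusted p = 0.00827), and its call was lost without ssi2 sid2 replicate 3 (0.0507), from a range of 0.000598 to 0.0507. HYH and AT2G15020 were also higher in ssi2 sid2 than in ssi2 act1, with -4.73 and -5.87 for ssi2 act1 minus ssi2 sid2 (adjusted p = 0.00377 and 0.00449), and both calls held under every alternative. Within ssi2 alone HYH stood at 9.19, 9.59 and 7.08 and AT2G15020 at 8.46, 8.73 and 4.19 in replicates 1, 2 and 3. UGT78D2, a flavonoid glucosyltransferase gene, had -3.28 (SE 0.561, adjusted p = 0.00657, up to 0.043).

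The actin control probe set AFFX-r2-At-Actin-3_s_at had a mean signal of 9998 in wild type, 1220 in ssi2, 1582 in ssi2 act1 and 1513 in ssi2 sid2, with log2 differences of -3.0, -2.65 and -2.69 from wild type (limma adjusted p = 6.14e-05, 0.0011 and 0.000432). The middle probe set of the same transcript, AFFX-r2-At-Actin-M_s_at, had -1.03, -0.70 and -1.02 (adjusted p = 0.0767, 0.42 and 0.0977). The probe set for the 5' end of the same transcript, AFFX-r2-At-Actin-5_s_at, had -0.34, -0.23 and -0.24 (adjusted p = 0.649, 0.896 and 0.814). Another actin 3' probe set, AFFX-Athal-Actin_3_f_at, had -2.70, -2.55 and -2.75 (adjusted p = 7.73e-05, 0.0011 and 0.000432). Its middle and 5' counterparts did not pass the threshold in any line. The ratio of GAPDH 3' to 5' signal lay between 0.912 and 1.28 on all arrays. A difference between the lines was not separated from the mutations here either.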
